A study of Oryza sativa with 6 samples.

How the data were processed

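RNA was extracted with Trizol from whole rice seedlings, messenger RNA was selected with oligo(dT) beads, and strand-marked (dUTP) libraries were sequenced as paired ends on an Illumina instrument, per the labels' protocols. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR, without roles or order. The genome build, the annotation and whether the strand was used in quantification are not given in the sources used here, so overlapping, antisense and near-identical loci cannot be told apart with certainty. The deposited table holds FPKM values, computed by the authors per locus, with a column per library and no pooling of replicates. It has 55626 loci, of which 54725 have identifiers of the LOC_Os form and 901 are named as new genes. Of all loci, 24484 are at 0 in every library. The FPKM columns sum to between 821699 and 871966. Low values were examined for steps that would give the relative depth of the libraries. Among 716 loci above 0 in all libraries and below 0.3 FPKM, at most 2.4% of the ratios to control replicate 1 fell within a single bin of 0.02 on the log2 scale, so no step was usable. Depth is therefore unknown, and no counting intervals are given.

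Each column was assigned to its sample by the library name in the labels, and each sample to control or inoculated by its title. The comparison, its test, the alternatives, the gene groups and the rule for named genes were fixed before the data were examined. Loci with a mean of at least 1 FPKM over the 6 libraries were kept, which left 21191, of which 575 were new loci. The values were analysed as log2(FPKM + 1), so that log2 changes understate the change of weakly expressed loci. Group means were compared with limma 3.58.1 in R 4.3.3, using an empirical Bayes variance trend, two-sided tests and Benjamini-Hochberg adjustment, with adjusted p under 0.05 as the threshold. Standard errors are limma's moderated ones. The fit was tested on simulated data with the means and spread of the real loci, where 200 loci were changed. It gave 6 calls among unchanged loci out of 122, and no call when no locus was changed. The simulated noise was independent between loci, so this check does not cover variation that the loci of a library share.

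The reference gene table, of assembly ASM3414082v1, was used only for names. After removal of the LOC_ prefix, 1 of the 54725 annotated identifiers matched it. The 32 gene groups therefore had no members that could be matched, and their tests, including camera and fry, were not run. The rule for named genes required an informative name, so no gene passed it. In its place, the 2 annotated loci with the largest rise and the 2 with the largest fall are printed by identifier, among changed loci with at least 5 FPKM in the higher group and separate group ranges. Chromosome numbers and the order of loci were read from the identifiers.

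Changed loci were compared between chromosomes, and between new and annotated loci, with Fisher's exact test, adjusted over 13 tests. Positions of changed loci were compared with 10000 random placements among tested annotated loci. These groupings were chosen after the data were seen. Other calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1. The alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, median-ratio scaling, scaling to a sum of 1000000, quantile normalization, no variance trend, robust empirical Bayes, sample weights, a replicate block, and leaving out each library in turn. Leaving out loci at 0 in any library and leaving out new loci were added after the data were seen. No 2 columns held identical values.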

Results

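Messenger RNA was measured by sequencing in whole rice seedlings (Oryza sativa) from 6 libraries. The 3 inoculated libraries came from plants placed for 6 h in Enterobacter sp. CS8-gfp, a bacterium that the series title describes as growth-promoting. The 3 control libraries came from plants given sterile water. In the sample records used here the 6 h is entered for inoculated plants only, so a matched time for the controls is not established. All plants had been germinated in the dark for 2 d and grown in hydroponic culture for 14 d. The series title concerns breakdown of the herbicide atrazine and the insecticide thiamethoxam in rice, but no label of these 6 libraries mentions either compound, so the comparison made here is inoculated against uninoculated plants. The labels do not say whether replicates came from separate plants or pools, so the p-values measure only the spread between these libraries.

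The table listed 55626 loci as FPKM (fragments per kilobase of transcript, scaled to each library's sequencing depth), of which 54725 carried rice annotation identifiers and 901 were named as new loci. Read counts per library were not part of the table, so the sequencing depth behind each value is unknown. Between 27004 and 27886 loci per library lay above 0, and between 20872 and 21175 reached 1 FPKM. Loci above 0 averaged 27316 ± 271 (SD, n = 3) in control and 27663 ± 219 (SD, n = 3) in inoculated libraries, and the ranges overlapped. The 10 most abundant loci held from 12.1% to 13.5% of the summed FPKM in the 3 control libraries and from 10.8% to 12.8% in the 3 inoculated libraries. The new loci together held 1.00% ± 0.0416 (SD, n = 3) and 1.02% ± 0.0378 (SD, n = 3).

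The transcriptomes of the 2 groups were close to each other. Across the 21191 tested loci, Pearson correlations of log2(FPKM + 1) ran from 0.968 to 0.978 for the 6 pairs of libraries within a group and from 0.961 to 0.970 for the 9 pairs between groups. These correlations are across loci, which are not independent replicates. On the same scale, a pair of libraries differed by more than 2-fold at 441 to 675 loci within groups. Between groups, the number was 618 to 877. The first principal component, with 29.6% of the variance, separated all 3 control libraries from all 3 inoculated libraries. The second, with 21.6%, spread the control libraries from -34.2 to 29.7.

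**Figure D1:**
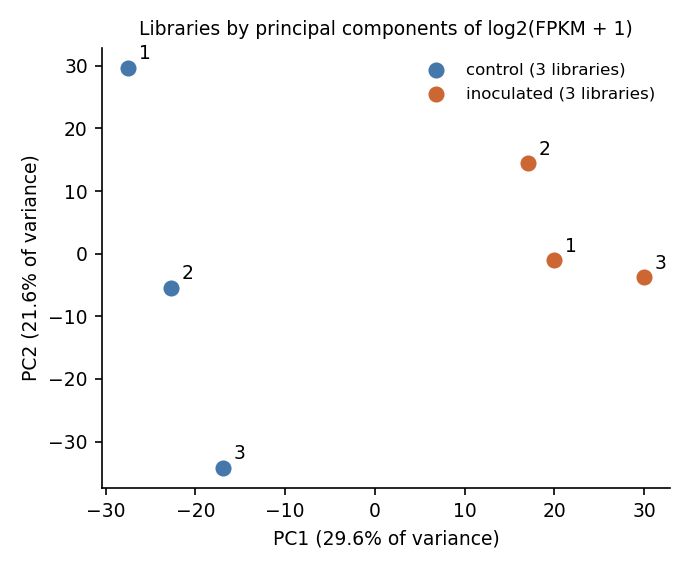
Each point is a library, placed by its scores on the first (x axis, 29.6% of variance) and second (y axis, 21.6%) principal components of log2(FPKM + 1) over 21191 loci, with its replicate number beside it. Control libraries lie between -27.5 and -16.9 on the first component and inoculated libraries between 17.1 and 30.

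Few loci passed the adjusted test between inoculated and control plants, and most of those that did were higher after inoculation. Of the 21191 loci tested, 53 were higher and 16 were lower in inoculated plants (limma, two-sided, Benjamini-Hochberg adjusted p under 0.05). Of these 69 loci, 63 changed by 2-fold or more on the log2(FPKM + 1) scale, 49 upward and 14 downward. On that scale, a change of at least 4-fold was reached by 29 higher and 5 lower loci. The median change was 2.12 on the log2 scale among the higher loci and -1.27 among the lower ones. In all 69 loci the values of the 2 groups did not overlap, which adds little because the test selected them on the same values. Of all tested loci, 16.5% had separate group values, against 10% by chance for 3 against 3. Without inoculated replicate 3 the test called 44 loci, 37 higher and 7 lower.

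The changed loci covered the whole range of expression levels. Those with a mean of 1 to 5 FPKM numbered 22 higher and 7 lower among 6736 tested. Between 5 and 20 FPKM, 16 were higher and 4 lower among 8168. Between 20 and 100 FPKM, 10 were higher and 4 lower among 5014. At 100 FPKM and above, 5 were higher and 1 was lower among 1273. The changed locus with the highest level in inoculated plants, on chromosome 7, rose from 357 ± 37.3 FPKM to 1778 ± 510 FPKM (SD, n = 3 each), which is 4.98-fold (limma adjusted p = 0.00625). The changed locus with the highest level in control plants, on chromosome 11, fell from 418 ± 47.3 FPKM to 228 ± 10.8 FPKM (SD, n = 3 each, limma adjusted p = 0.0280). A chromosome 12 locus rose 12.7-fold, from 24.0 ± 3.19 FPKM to 306 ± 25.8 FPKM (SD, n = 3 each, limma adjusted p = 3.5e-05). These 3 loci were chosen after their values were seen.

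**Figure D2:**
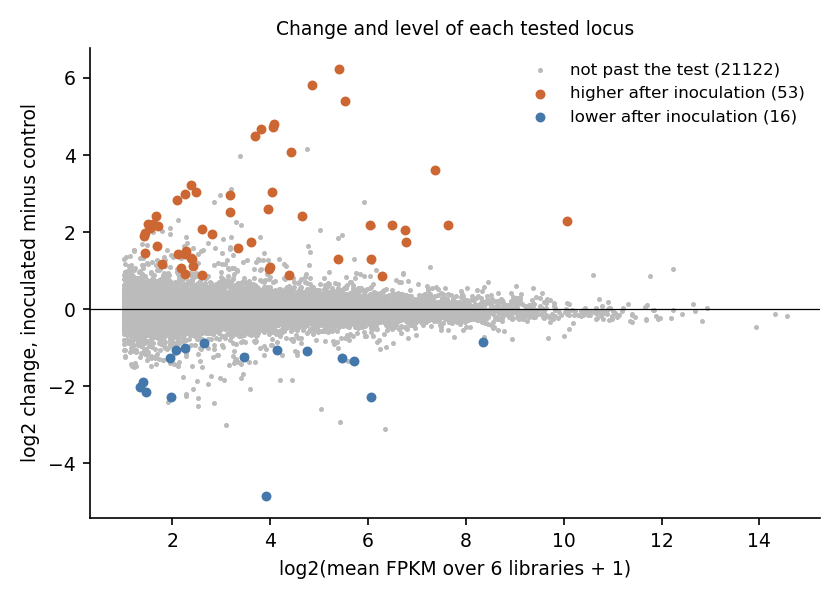
Each point is a tested locus, with log2 of its mean FPKM over 6 libraries plus 1 on the x axis and its log2 change, inoculated minus control, on the y axis. The 53 loci that were higher and the 16 that were lower in inoculated plants (limma, adjusted p under 0.05) are coloured, and the remaining loci are grey.

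Some of the largest rises and falls were close to complete, and others were not. A chromosome 4 locus with a log2 change of -2.29 ± 0.177 (SE) still held 21.4 ± 2.94 FPKM in inoculated plants. Its control level was 109 ± 25.5 FPKM (SD, n = 3 each, limma adjusted p = 0.00308). LOC_Os03g18779, on chromosome 3, stood at 0.119 ± 0.113 FPKM in control and 82.9 ± 6.01 FPKM in inoculated plants (SD, n = 3 each), a rise of 6.23 ± 0.112 (SE) on the log2(FPKM + 1) scale (limma adjusted p = 1.24e-06). LOC_Os01g61340, on chromosome 1, was listed at 0 in all 3 control libraries and at 51.6, 58.6 and 57.5 FPKM in inoculated replicates 1, 2 and 3 (limma adjusted p = 1.24e-06). LOC_Os11g40760, on chromosome 11, showed the opposite pattern, with 33.2, 25.6 and 26.2 FPKM in control replicates 1, 2 and 3 and a listing at 0 in all 3 inoculated libraries (limma adjusted p = 1.4e-05). LOC_Os11g31590, also on chromosome 11, fell from 5.46 ± 1.11 FPKM to 0.354 ± 0.474 FPKM (SD, n = 3 each), by 2.29 ± 0.269 (SE) on the log2 scale (limma adjusted p = 0.0205). Its call was lost in 5 of the 6 fits that left out 1 library, all but the fit without inoculated replicate 1, with limma adjusted p from 0.0562 to 0.127, while the log2 change in those 5 fits stayed between -2.44 and -2.11. The call was also lost with a pseudocount of 0.1 (log2 change -4.19, limma adjusted p = 0.142) and with no expression filter (log2 change -2.29, limma adjusted p = 0.0775).

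**Figure D3:**
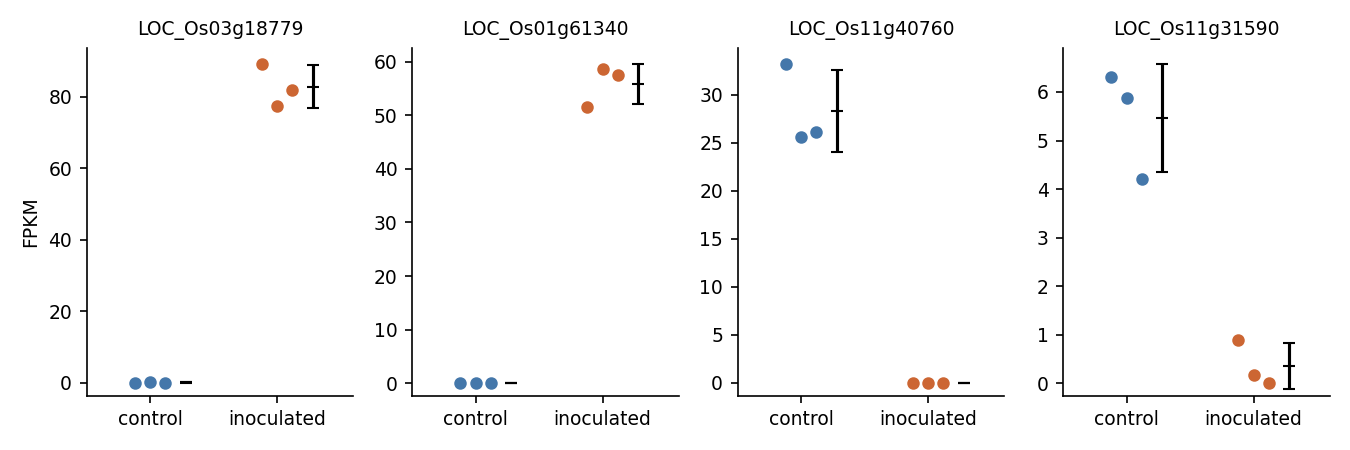
FPKM (y axis, a separate linear scale per panel) of the 2 printed loci that rose most and the 2 that fell most, in each control and inoculated library (points), with the mean and SD of each group beside them as a bar. In all 4 panels the control and inoculated points are separate, and LOC_Os11g40760 is listed at 0 in all 3 inoculated libraries.

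A group of 15 loci, defined after the values were seen, lay at 0.1 FPKM or less in every library of a group and at 1 FPKM or more in every library of the other. Of these, 11 were expressed in inoculated plants and 4 in control plants. In 11 of the 15, every library of the silent group was listed at exactly 0. The test called 10 of them, 3 were below the expression filter, and 2 were tested and did not pass. An exact 0 in such a table can be a failed estimate. With the same limits, 39 other loci lay at 0.1 FPKM or less in a single library while the remaining 5 all held at least 1 FPKM. In 3 of these the remaining 5 libraries all held at least 10 FPKM.

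The new loci contributed 5 of the 69 calls, all 5 higher in inoculated plants, from 575 tested. That count was 2 with a filter of 5 FPKM and 2 when loci at 0 in any library were left out, settings that test fewer loci. Annotated loci contributed 64 calls from 20616 tested, 48 higher and 16 lower. The odds ratio for new loci was 2.82 (95% interval 0.881 to 6.96, Fisher's exact test, two-sided, p = 0.0393), and the adjusted p over 13 such tests was 0.23. The interval, which is computed in another way than the p, includes no difference. Tested new loci had a median of 4.08 FPKM against 9.79 FPKM for annotated ones, and the comparison was not matched for level. The most abundant of the 5 rose from 40.7 ± 5.96 FPKM to 172 ± 8.71 FPKM (SD, n = 3 each, limma adjusted p = 0.000668).

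Changed loci were found on all 12 chromosomes, as read from the identifiers. Chromosome 1, which had the most tested loci (2942), held the most, with 10 higher and 1 lower against 9.13 expected. Chromosome 7 held 6 higher and 3 lower, against 4.75 expected from the number of loci tested there. Chromosome 12 held 6 higher and 1 lower against 3.43 expected, and chromosome 2 held 2 higher and none lower against 7.57 expected. None of the 12 chromosomes passed Fisher's exact test after adjustment over the 13 tests, where the smallest adjusted p was 0.23.

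In all, 2042 loci (9.64% of those tested), the 69 changed loci among them, had an unadjusted limma p under 0.05. On the log2(FPKM + 1) scale, 26 loci changed by 4-fold or more without passing the adjusted test. Of these, 14 were higher and 12 lower. The median standard error of a log2 change was 0.138. In simulated data of 21191 loci with the spread of these libraries, the test recovered 25.4% of 1.5-fold changes, 58.2% of 2-fold changes and 90.9% of 4-fold changes. These folds were set on the log2(FPKM + 1) scale, where an FPKM change of a weakly expressed locus is smaller. The simulation also gave 122 calls against 69 here, which makes the adjusted threshold easier to pass. Both differences would make recovery of FPKM changes lower in the real data. The simulated spreads were drawn from observed ones, which carry sampling error of their own, and this could act the other way. The net effect was not measured. In the simulation, smaller changes were often missed with 3 libraries per group.

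The table gives no gene names, and functions of the changed loci are therefore not described. None of the 32 gene groups set out before the data were examined could be counted, among them cytochrome P450 enzymes, glutathione S-transferases, glycosyltransferases, ABC transporters, pathogenesis-related proteins, hormone response genes, root markers and the light-harvesting genes chosen to mark shoots. A single identifier could be matched to a name, OsCCC2, and that locus lay below the expression filter at 0.122 ± 0.0333 FPKM in control and 0.162 ± 0.0706 FPKM in inoculated plants (SD, n = 3 each).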

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

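All 69 changed loci kept their direction in each of the 18 alternative fits in which they were tested. Their group values did not overlap, so only the 3 other scalings could have reversed a direction, and the remaining fits could not. Scaling moved the median change of all loci from 0.033 to between -0.003 and 0.058 on the log2 scale. The total stayed between 63 and 74 under a pseudocount of 0.1, no filter, 3 other scalings, no variance trend, robust empirical Bayes and sample weights. With no filter, 9 loci were lower in place of 16, and 47 of the 69 calls were kept. A filter of 5 FPKM, which tests fewer loci, called 38 (30 higher, 8 lower, 35 of them by 2-fold or more), and 38 of the 40 calls it could test were kept. Leaving out 1 library at a time gave 44 to 55 calls, 37 to 44 higher and 7 to 11 lower, and 44 to 55 by 2-fold or more. The lowest total came without inoculated replicate 3, and 38 loci were called in all 6 of these fits. The lower count was 8 without control replicate 2 or control replicate 3, 9 without inoculated replicate 2 and 7 without inoculated replicate 3. Leaving out a library leaves 2 against 3, and the cause of the lost calls was not otherwise tested. No pairing of the libraries by replicate number was seen, though 3 libraries per group cannot exclude one. Same-numbered libraries had deviation correlations of -0.052, -0.008 and 0.04, and 1 of the 6 libraries correlated best with its own number. A replicate block called 48 loci, 41 higher and 7 lower, of which 43 were among the 69. The printed loci LOC_Os03g18779, LOC_Os01g61340 and LOC_Os11g40760 were called in every alternative run that tested them. Without loci at 0 in any library 57 were called, and without new loci 64, both chosen after the data were seen. The alternatives planned for the gene groups were not run, because no group could be matched to identifiers. Without counts, the part of the spread that comes from depth cannot be separated.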

Other observations

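The tests in this part were all chosen after the results they bear on had been seen. Annotated loci that changed lay in places close together in the order of tested loci. That order holds 20616 of the 54725 annotated loci, so a pair close in it need not be adjacent on the chromosome. Of the 64 changed annotated loci, 12 formed 6 pairs lying within 3 places of each other in the order of tested loci, on 4 chromosomes. In 4 pairs both loci were higher in inoculated plants and in 2 both were lower. On chromosome 11 all 4 changed loci were lower and none was higher. Of these 4, 2 form one of the 6 pairs, and whether the 4 changed independently was not tested.

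The 69 changed loci of the real grouping compare with at most 3 in the 9 other splits of the 6 libraries into 3 and 3, and the real split was the only 1 of the 10 to reach that number. The 2042 loci with an unadjusted p under 0.05 compare with at most 1658. With 10 splits no share under 0.05 can be had.

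The first pattern is the set of 15 loci silent in every library of a group and expressed in every library of the other. The real split was the only 1 of the 10 to give that many, the highest other split gave 8, and 10 splits are too few for a share under 0.05. Estimates that drop to 0 at random in libraries would give each split a similar number, but the 9 other splits averaged 4.56, so such zeros may account for some of the 15, while that average argues against them as the whole cause. A shift of reads to the adjacent locus found no support, since 0 of 13 annotated loci had a neighbour moving the other way by a comparable amount (exact 95% upper bound 24.7%), although a long neighbour would show a smaller FPKM change and new loci have no position here. A single chromosome block differing between the sets of seedlings would hold most of these loci, but at most 2 of the 10 tested annotated ones lay within a stretch of 50 loci, and the 13 annotated loci were spread over 8 chromosomes. Scattered sequence differences between the sets of seedlings, a response to the bacterium and any other difference shared by all libraries of a group stay open. None of these was tested. The genotype field of the labels only repeats the treatment codes, and the cultivar is not given in the sources used here.

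The second pattern is the closeness of changed loci in the order of tested loci. It had been noticed in the list of changed loci before it was tested, so the distances tried are not independent of it. At a distance of 20 tested loci, 6 pairs were seen against 3.86 on average in random placements (permutation p = 0.191, one-sided). All 6 lay within 3 places, so this wide distance could hide closeness at short range and does not decide for independent positions. At 5 loci the 6 pairs compare with 0.98 (permutation p = 0.0007, one-sided, and 0.0028 after adjustment over 4 distances), at 10 loci with 1.94 (adjusted p = 0.0332), and at 50 loci 15 pairs compare with 9.58 (adjusted p = 0.0847). The short distances restate what had been seen, so whether changed loci lie closer together than independent positions would put them stays open. Reads shifted from a locus to its adjacent one would move the 2 in opposite directions, which 0 of 6 pairs did (exact 95% upper bound 45.9%). Judged by their identifiers, however, some of the pairs have untested loci between them, so reads would not shift within those. Adjacent pairs were not tested apart, and no conclusion on shifted reads is drawn. Reads shared between near-identical copies near each other and joint regulation of nearby loci also stay open, because the table holds no sequences.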
